A study of Mus musculus with 10 samples.

How the data were processed

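Polyadenylated RNA from mouse cells was sequenced in 2 experiments. In the first, N2A cells, a mouse neuroblastoma line, received an siRNA pool against Qk (siQk, n = 3) or a non-targeting pool (siNT, n = 3) at 40 nM, and RNA was taken 72 h later from wells seeded with 100000 cells. In the second, glutamatergic neurons made from mouse embryonic stem cells were left untreated (n = 2) or given 100 uM cycloheximide for 12 h on day 7 in culture (n = 2). Per the labels' protocols, the libraries were stranded and were made with longer inserts than usual, and the replicates are biological replicates. The software behind the deposited tables is not given in the sources used here. Coordinates are on mm10, per the submitters' processing notes.

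The main table gives, per the file headers, a deposited percent spliced in (PSI) for each splicing event and N2A sample, in the format of a vast-tools table. PSI is the share of transcripts that include the exon, intron or splice site. Beside each percent the authors deposited a quality cell in text form (another kind of value) with the inclusion and exclusion reads of that event, not scaled to library size. The table held 192593 exon events, 189134 introns, 155519 alternative 3' splice sites and 123916 alternative 5' splice sites. The authors also deposited a list of neural microexons with the PSI of each group as a fraction, replicates combined, a class for the response to Qk and the side on which an ACTAAY motif lies (Y is C or T). Neither the window of that motif search nor the rule behind the classes is given in the sources used here. For the neurons, the authors deposited a comparison of microexons in the format of a Whippet table, with a PSI fraction per condition (replicates combined), a probability of a difference as a fraction and an entropy score, which was not used here. Its first PSI column was taken as untreated because the table's name puts the control first. All PSI values are printed in percent.

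Each event entered with at least 10 inclusion plus exclusion reads in each of the 6 N2A samples and a mean PSI from 2 to 98. The log2 ratio of inclusion to exclusion reads, each plus 0.5, was compared between siQk and siNT with limma 3.58.1 in R 4.3.3 (robust moderated test, variance trend on the mean log sampling variance, two-sided). P-values were adjusted by Benjamini-Hochberg within each event class, and cassette exons of all lengths shared 1 fit. An event was called changed at an adjusted p under 0.05 with a difference of mean PSI of at least 10 percentage points. Microexons are cassette exons of 3 to 27 nt. The 2 sites of an alternative splice site pair are separate events and are not independent. Each event was also required to have a gene name to be named in the text.

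Reads of the exon events of each gene were summed as a stand-in for gene expression, since no gene counts were used here. A read can serve several events and is then counted more than once. These sums were divided by the sample total (CPM), and log2(CPM + 0.5) was tested with limma's trend method over genes with a mean of at least 20 reads. Fold changes on this scale understate the change of genes with low coverage. Gene lists were written before the data were examined, from general knowledge: 6 for splicing and 7 for junction coverage. Splicing lists were compared by Fisher's exact test on genes with at least 1 called cassette exon, against all other genes with a tested cassette exon. Coverage lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. P-values of the lists were adjusted over the lists of each kind. All Fisher tests were exact and two-sided, and exons and genes in them are not independent replicates.

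In the neurons a microexon was counted as changed at a difference of at least 10 percentage points and a probability of at least 0.9 in the authors' comparison. That rule returns the same exons as a second, filtered table the authors deposited. No test across the 4 neuron samples was run, because the table holds combined values only. The read depth behind these values is unknown, and 2 samples against 2 could not give an exact permutation p below 0.33. Microexons of the experiments were matched by chromosome, start and end. Exon positions were looked up in the GENCODE M21 annotation of the same assembly. Tables and figures were made with Python 3.11.15, pandas 2.3.3, matplotlib 3.10.9 and version 1.17.8 of data.table.

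Exon-event reads numbered 59997671, 37883497 and 78479832 in siNT samples 1 to 3 and 33761573, 26595944 and 80481173 in siQk samples 1 to 3. The median reads per tested microexon were 156.5, 99 and 211.5 in siNT and 87.5, 67 and 190.5 in siQk. PCR copies cannot be told from separate molecules in such reads. Within groups, the pairs of samples differed by 1.62 to 4.28 times the sampling variance, so no sample is a copy of another. The scripts were tested on simulated data with known changes. Of exons simulated with a difference of 10, 20, 30 or 40 percentage points, 6%, 46%, 70% and 96% were called, with 1 false call among 110 over 11290 exons. For junction coverage all simulated changes of 2-fold and 4-fold were called, with 8 false calls among 208 over 10828 genes. These changes were placed only in genes with more reads than the filter asks for. Both simulations used a fixed spread between samples that was not estimated from the data, so recovery in the real samples can differ.

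Named events follow a rule set before the data were examined, among calls in which all 3 siQk samples lie on 1 side of all 3 siNT samples, a separation that chance gives in 10% of features. It takes the 8 microexons with the largest rise and the 8 with the largest fall, 6 and 6 longer exons, 2 and 2 of each other class, 6 and 6 genes by coverage besides Qk, and up to 4 called members of each gene list. Some items that the rule names are not reported here. From the neurons it takes the 8 changed microexons with the largest rise and the 8 with the largest fall, and it takes all microexons changed in both experiments. Alternatives covered the read minimum, the PSI range, the pseudocount, the scale and weights of the test, the rule for a call, the deposited quality class, a replicate block, the microexon length, each sample left out in turn, the scaling and filters of junction coverage and the thresholds in the neurons. A planned search for the motif in intron sequence was not run, because no genome sequence was used here. The deposited motif column took its place after the data were seen. A narrower gene background, reads thinned to the shallowest library, a minimum intron inclusion, the motif over the whole list and cassette exons alone in the neurons were also added then.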

Results

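RNA sequencing measured splicing in 6 samples of N2A mouse neuroblastoma cells (3 siNT controls and 3 with Qk knocked down) and in 4 samples of neurons made from mouse embryonic stem cells (2 untreated and 2 with cycloheximide, an inhibitor of translation). The total of exon-event reads ran from 26595944 to 80481173 per N2A sample. The depth of the neuron samples is unknown. The first comparison asks which exons, and above all which microexons, depend on Quaking (Qk), an RNA-binding regulator of splicing. The second asks which microexon isoforms differ when translation, and with it nonsense-mediated decay, is blocked. All values are mean PSI ± SD with n = 3 per group for the N2A cells unless stated, positions are on mm10, and adjusted p-values are from limma.

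Qk itself was reduced in every siQk sample. Its junction coverage was 85.4 ± 4.71 CPM (SD, n = 3) in siNT and 11.2 ± 2.60 CPM (SD, n = 3) in siQk, so that 13.1% remained. The log2 fold change was -2.91 (SE 0.16, limma adjusted p = 0.000301).

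Knockdown of Qk raised the inclusion of many microexons and lowered that of a few. Of 410 microexons tested, 30 changed: 25 rose and 5 fell. Adjusted over the list alone, 63 changed, 54 upward and 9 downward. The microexon with the largest rise lay in Nrxn2, which encodes the synaptic adhesion protein neurexin 2: its 17 nt exon (MmuEX0032385, chromosome 19, 6463831 to 6463847) went from 8.27% ± 1.54 in siNT to 69.0% ± 5.18 in siQk (adjusted p = 0.000119). A 12 nt coding exon of Ank2 (MmuEX0004898, chromosome 3, 126979256 to 126979267), which encodes a protein that ties membrane proteins to the spectrin skeleton, rose from 25.2% ± 6.35 to 80.9% ± 5.70 (adjusted p = 0.00102). Both liprin-alpha genes with a large change, Ppfia1 and Ppfia3, encode scaffold proteins of adhesion sites and synapses. The 27 nt coding exon of Ppfia1 (MmuEX0036499, chromosome 7, 144488691 to 144488717) rose from 20.1% ± 1.28 to 73.1% ± 3.08 (adjusted p = 5.00e-05). The 27 nt coding exon of Ppfia3 (MmuEX0036514, chromosome 7, 45343553 to 45343579) rose from 27.6% ± 7.82 to 76.5% ± 5.76 (adjusted p = 0.0065).

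The other named rises were in genes of the cytoskeleton and the Golgi. A 24 nt exon of Clasp1, a microtubule plus-end protein, rose from 4.61% ± 1.66 to 36.4% ± 7.05. A 12 nt exon of the Golgi ion pump gene Atp2c1 rose from 27.5% ± 7.26 to 57.8% ± 4.35. An 18 nt exon of Dst, a linker between cytoskeletal filaments, rose from 60.3% ± 2.86 to 89.99% ± 2.70, and a 27 nt exon of the kinesin gene Kifc3 rose from 68.8% ± 3.06 to 94.4% ± 2.65. Their adjusted p-values ran from 0.000826 for Clasp1 to 0.0118 for Atp2c1. Further microexons that rose were in Ap1b1, Sh3glb2, Arvcf, Trrap, Pus7, Nckap1, Dctn1, Cacnb1, Eprs, Ckap5, Gramd1a, Bin1, Col4a1, Mta1, Sh3glb1, Tenm3 and Ppp6r3.

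The 5 microexons that fell lay in Map3k6, Ncam1, Mroh1, Mark3 and Incenp. A 24 nt exon of the kinase gene Map3k6 (chromosome 4, 133243053 to 133243076) went from 97.9% ± 2.32 to 56.7% ± 12.5 (adjusted p = 0.00895). A 3 nt exon of the adhesion gene Ncam1 (chromosome 9, 49540415 to 49540417) went from 76.5% ± 0.588 to 44.7% ± 1.61 (adjusted p = 0.00119). Neither the Ncam1 exon nor the Nrxn2 exon has its exact ends in the GENCODE M21 annotation. A 27 nt exon of Mroh1 went from 86.7% ± 4.88 to 68.8% ± 4.48 (adjusted p = 0.0473), and a 27 nt exon of Mark3, a kinase of microtubule-associated proteins, went from 13.6% ± 1.62 to 0.61% ± 0.796 (adjusted p = 0.00701). A 12 nt exon of Incenp, a member of the chromosomal passenger complex, went from 21.4% ± 4.25 to 10.1% ± 0.803 (adjusted p = 0.0252).

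**Figure D1:**
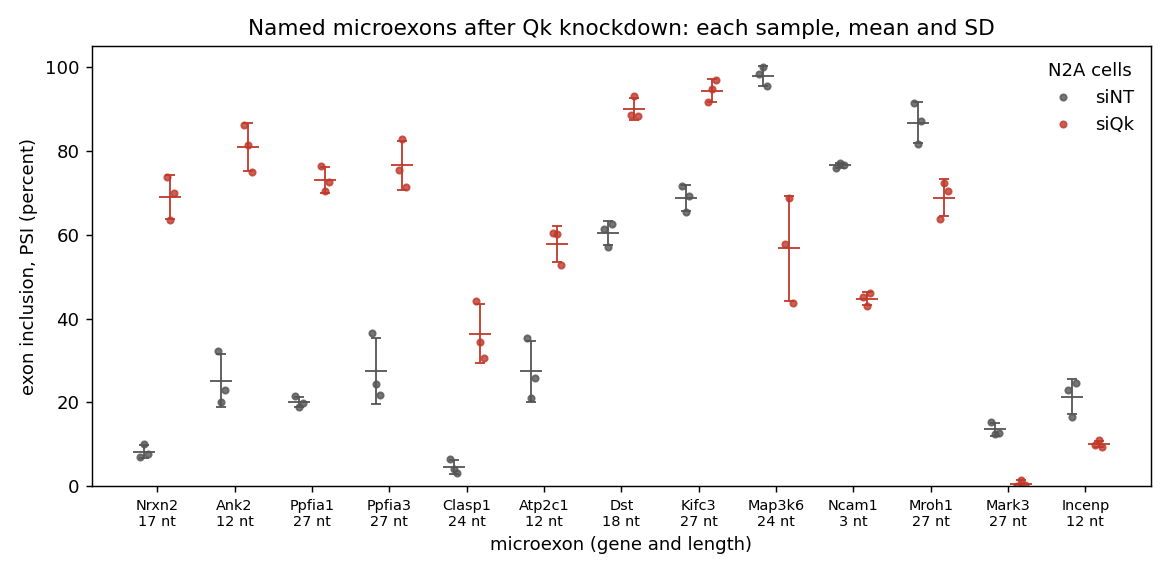
Inclusion (PSI, percent) of the named microexons in each siNT and siQk sample of N2A cells, with points for samples and bars for the mean and SD (n = 3). The siQk samples of Nrxn2 average 69.0% against 8.27% in siNT, and the Ncam1 exon goes the other way, from 76.5% to 44.7%.

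Microexons changed more often than longer cassette exons. The share called was 7.32% of microexons and 0.975% of 12519 longer exons (odds ratio 8.02, 95% interval 5.12 to 12.2, Fisher's exact p = 5.52e-16). Called microexons rose more often than called longer exons did (odds ratio 3.45, 95% interval 1.19 to 12.3, Fisher's exact p = 0.0185). The count of microexons changed by Qk knockdown was 17 without siNT 2, 17 without siNT 3, 19 without siQk 2 and 17 without siQk 3, 46 with limma on PSI, 47 with sampling variance weights and 46 with a rule of 15 points and no p-value; in the direction of change, microexons against longer cassette exons, the odds ratio was 2.52 without siNT 2 (Fisher's exact p = 0.168). The calls of Mroh1, Incenp, Mark3, Atp2c1, Kifc3 and Map3k6 were each lost when at least 1 of the samples was left out.

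**Figure D2:**
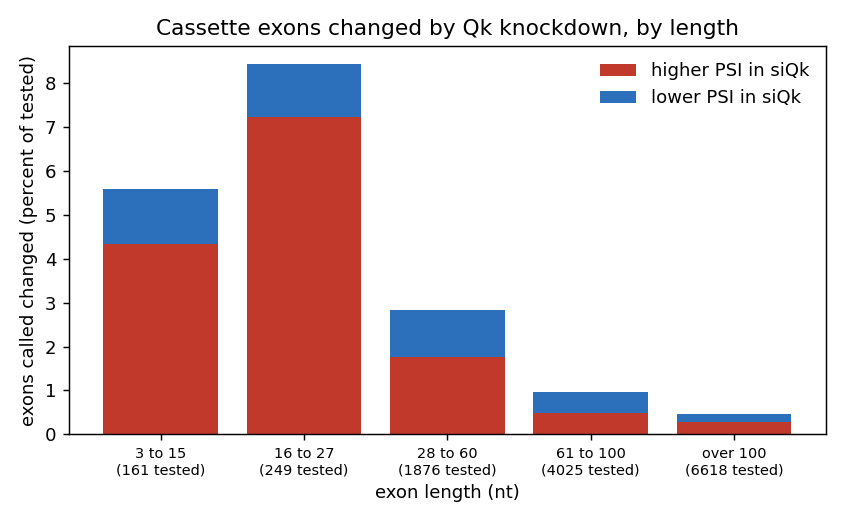
Share of tested cassette exons (percent) called changed after Qk knockdown, by exon length in nt, with higher PSI in siQk in red and lower PSI in blue. The share is 8.43% at 16 to 27 nt and 0.453% above 100 nt.

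Among longer cassette exons, 122 changed: 72 rose and 50 fell. The exons with the largest rises were a 45 nt exon of Fryl (15.1% ± 6.24 to 86.2% ± 9.70, adjusted p = 0.0033) and a 129 nt exon of Adgrl2, which encodes the adhesion receptor latrophilin 2 (10.7% ± 0.448 to 74.2% ± 2.92, adjusted p = 2.52e-05). A 144 nt exon of the scaffold gene Erbin rose from 26.3% ± 3.87 to 81.0% ± 0.377 and a 283 nt exon of Ksr1, a scaffold of the MAP kinase pathway, from 34.9% ± 6.97 to 86.6% ± 12.8. A 116 nt exon of Fkbp7 rose from 38.7% ± 2.84 to 89.9% ± 4.79, with as few as 12 reads in a sample. A 36 nt exon of Mbnl2, itself a splicing regulator, rose from 8.21% ± 0.285 to 54.0% ± 5.78 (adjusted p = 0.000145).

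The longer exons with the largest falls included 57 nt coding exons of a pair of neuronal membrane proteins. That of Clstn1 (chromosome 4, 149641658 to 149641714), which encodes calsyntenin 1, went from 89.0% ± 1.68 to 17.8% ± 0.210 (adjusted p = 2.61e-07). That of the adhesion gene Nrcam (chromosome 12, 44545379 to 44545435) went from 89.1% ± 1.87 to 18.1% ± 5.46 (adjusted p = 0.00324), with as few as 13 reads in a sample. A 54 nt exon of the centrosome and Golgi scaffold gene Akap9 went from 66.5% ± 5.77 to 3.67% ± 2.45 and a 48 nt exon of Uap1, an enzyme of amino sugar synthesis, from 86.6% ± 1.87 to 30.3% ± 1.31. A 63 nt exon of the actin regulator Evl went from 76.1% ± 2.50 to 24.6% ± 5.02. A 79 nt exon of Srrm3, which encodes an activator of neural microexons, went from 66.0% ± 11.6 to 3.84% ± 3.41 (adjusted p = 0.0063), and its exact ends are not in GENCODE M21. The number of longer cassette exons changed by Qk knockdown was 66 without siNT 2 and 75 without siNT 3. The calls of Ksr1 and Fkbp7 were lost without any 1 of the siNT samples, that of Ksr1 also without siQk 2, and that of Srrm3 without siNT 2.

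Genes of the cytoskeleton and of cell adhesion held changed exons most often among the 6 lists. A changed cassette exon was found in 12 of 37 tested genes of the list of cytoskeleton and adhesion genes (odds ratio 21.1, 95% interval 9.43 to 44.8, Fisher's exact adjusted p = 1.63e-10). In these genes 15 exons rose and 3 fell, and adjusted over the list alone 22 rose and 7 fell. Besides Clasp1, a 111 nt exon of Dst went from 57.4% ± 3.72 to 12.1% ± 0.931, opposite to the 18 nt exon of the same gene. A 45 nt exon of Myo18a, an unconventional myosin, fell from 41.1% ± 1.97 to 8.47% ± 0.588.

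Endocytosis and vesicle traffic genes held a changed exon in 8 of 32 genes (odds ratio 14.2, 95% interval 5.41 to 33.5, Fisher's exact adjusted p = 1.84e-06), with 9 exons that rose and 1 that fell; adjusted over the list alone, 13 rose and 2 fell. Examples were a 30 nt exon of Arfgap1, which acts on the GTPase Arf (47.6% ± 4.13 to 83.3% ± 2.47), a 93 nt exon of the membrane-bending protein gene Bin1 (49.1% ± 3.43 to 81.0% ± 0.382), a 480 nt exon of Sgip1 (54.6% ± 8.45 to 84.3% ± 2.96) and a 139 nt exon of Dnm2, a dynamin (28.8% ± 1.77 to 56.5% ± 1.99). Neuronal microexon genes held a changed exon in 8 of 44 genes (odds ratio 9.45, 95% interval 3.72 to 21.2, Fisher's exact adjusted p = 1.62e-05), with 9 exons that rose and 3 that fell; adjusted over the list alone, 18 rose and 6 fell. Ank2, Ppfia1, Clasp1 and Nrcam are members of that list. The lists share members: of its changed genes, Clasp1, Dctn1 and Kif1b also count in the cytoskeleton and adhesion list. Dnm2 also counts in the endocytosis list, so the results of these lists are not independent. A gene with more tested exons has more chances to hold a called one, and these tests did not match genes on this. The neuronal microexon list was also made of microexon genes, and microexons were called more often than longer exons.

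The other 3 lists did not differ from the remaining genes beyond chance. Splicing regulators held a changed exon in 3 of 47 genes (odds ratio 2.79, Fisher's exact adjusted p = 0.156), namely Srrm3, Mbnl2 and Mbnl1; 1 exon rose and 2 fell, and adjusted over the list alone 1 rose and 3 fell. The 54 nt exon of Mbnl1 fell from 79.1% ± 0.530 to 59.0% ± 4.96. Autism-associated genes held one in 2 of 36 genes (odds ratio 2.39, Fisher's exact adjusted p = 0.259), Ank2 and Nckap1, both upward, with the same 2 exons adjusted over the list alone. The 18 nt exon of Nckap1, an actin regulator, rose from 72.5% ± 4.84 to 93.1% ± 1.22. Chromatin regulators held one in 1 of 36 genes (odds ratio 1.15, Fisher's exact adjusted p = 0.587), also when adjusted over the list alone: the 12 nt exon of Mta1, part of a histone deacetylase complex, rose from 80.0% ± 0.989 to 94.4% ± 2.29. In the gene list in splicing: autism-associated genes the odds ratio was 6.85 with no filter on mean PSI (Fisher's exact adjusted p = 0.00585) and 4.54 with the rule of 15 points (Fisher's exact adjusted p = 0.0116), and in the gene list in splicing: splicing regulators it was 4.0 without siQk 1 (Fisher's exact adjusted p = 0.0344). The call of Mbnl1 was lost without any 1 of the siNT samples or without siQk 2.

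**Figure D3:**
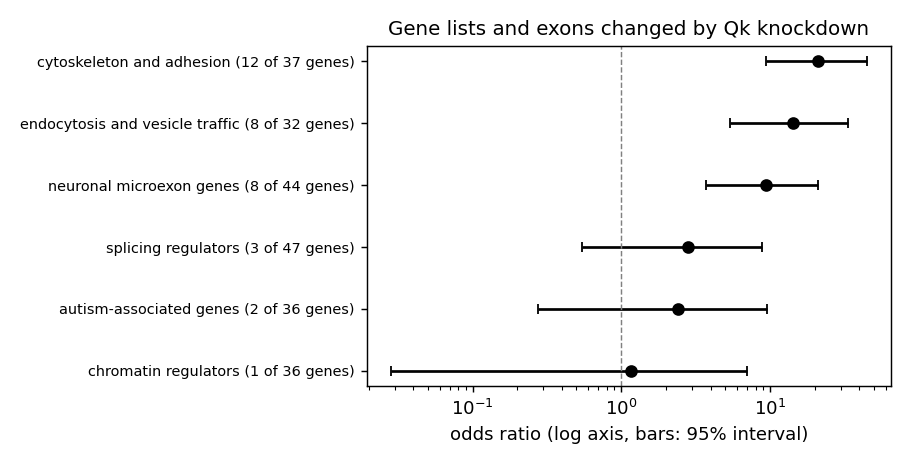
Odds ratio (log axis) of holding a changed cassette exon after Qk knockdown for each gene list against all other tested genes, with bars for the 95% interval and the number of changed and tested genes in brackets. Cytoskeleton and adhesion genes lie at 21.1 and chromatin regulators at 1.15.

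The authors' list of neural microexons moved upward. Of its 172 members with enough reads and a mean PSI from 2 to 98, 19 changed and all 19 rose. Adjusted over the list alone, 44 rose and 2 fell. The list's classes were set on these samples, so neither count is independent evidence of direction. List members changed more often than the other microexons tested (odds ratio 2.56, 95% interval 1.12 to 6.13, Fisher's exact p = 0.0199). Among its members, 41 are classed in the authors' deposited table as repressed by Qk and 2 as activated, while 89 and 94 members make up its pair of classes without a change. All 19 calls fall in the repressed class, and 24 members that the authors' deposited table classes as changed were not called. Across members, the difference of mean PSI correlated with the difference in the authors' deposited table (Pearson's r = 0.987), but exons are not independent replicates. Calls, classes and both differences come from the same 6 samples, so their match is no separate evidence. The excess over other microexons was lost without any 1 sample except siQk 1: in the deposited neural microexon list in the Qk knockdown the odds ratio was 2.30 without siNT 1 (Fisher's exact p = 0.0723), 1.59 without siNT 2 (Fisher's exact p = 0.453), 1.27 without siNT 3 (Fisher's exact p = 0.626), 2.08 without siQk 2 (Fisher's exact p = 0.151) and 1.99 without siQk 3 (Fisher's exact p = 0.211). It was 14.3 with no filter on mean PSI (Fisher's exact p = 1.85e-13), 4.09 with limma on PSI (Fisher's exact p = 2.33e-05) and 4.25 with sampling variance weights (Fisher's exact p = 1.30e-05). The list gave 8 calls without siNT 3, 9 without siNT 2, 10 without siQk 3, 11 without siQk 2, 33 with limma on PSI, 34 with sampling variance weights and 29 with the rule of 15 points.

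Among the tested members, those that rose carried the ACTAAY motif upstream more often than those not called. The authors' deposited table places the motif, a recognition core of Qk, upstream of 27 members and downstream of 15. It lay upstream of 7 of the 19 microexons that rose, among them those of Ppfia1, Ppfia3, Atp2c1, Sh3glb2, Cacnb1 and Col4a1, and of 10 of the 153 not called (odds ratio 8.16, 95% interval 2.22 to 29.3, Fisher's exact p = 0.000642). For the deposited upstream motif among list microexons that rose the odds ratio was 4.18 with the rule of 15 points, 4.38 with no filter on mean PSI, 5.25 with the adjusted p alone and 16.9 without siQk 3. The 54 members not tested hold 10 more upstream motifs in the authors' deposited table. Over the whole list, the authors' deposited table has the motif upstream of 9 of 41 repressed members and 18 of 183 without a change (odds ratio 2.56, 95% interval 0.929 to 6.68, Fisher's exact p = 0.0584). This comparison also put the authors' classes in place of the calls, so the lower ratio cannot be put down to the untested members alone. The difference is thus shown only for the calls among the tested members. Both comparisons were chosen after the data were seen.

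Fewer introns and alternative splice sites changed. Of 17664 introns tested, 20 changed, 11 with more retention in siQk and 9 with less. An 878 nt intron of Smarcc2, a subunit of the SWI/SNF chromatin complex, rose from 37.6% ± 1.93 to 81.1% ± 2.23 (adjusted p = 9.32e-14), and a 521 nt intron of Sspo rose from 39.9% ± 8.37 to 82.8% ± 4.93. A 667 nt intron of Ifi30, a lysosomal thiol reductase, fell from 70.1% ± 0.604 to 48.4% ± 4.89 and an 852 nt intron of the endocytic adaptor Eps15 from 41.5% ± 10.3 to 20.3% ± 3.00. In 5 of the 20 introns a called cassette exon lies inside, as in Ksr1 and Srrm3, so that the exon and the intron share reads. The called introns of Eps15, Ralgapa1, Tacc2 and Tradd border a called alternative splice site. That of Ralgapa1 and the 250 nt intron of Cacnb1 border a called cassette exon. All of these calls are not separate findings either.

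Of 9943 alternative 3' splice sites 10 changed, and of 7498 alternative 5' splice sites 8 changed, with equal numbers upward and downward. In Isg20, an exonuclease gene, one 3' site rose from 43.0% ± 5.51 to 78.1% ± 3.76 as another fell from 54.0% ± 5.29 to 21.9% ± 3.76. In Ralgapa1, sites 3 nt apart went from 8.19% ± 0.720 to 36.9% ± 13.6 and from 91.8% ± 0.720 to 63.1% ± 13.6. Among the 5' sites were those of Eps15, where the site beside the intron above rose from 42.7% ± 11.7 to 69.5% ± 5.71, and those of Gemin2, of the complex that assembles spliceosomal particles, where a site listed at 0 in every siNT sample reached 26.2% ± 10.2 while another fell from 98.6% ± 1.42 to 71.9% ± 10.7. Retained introns changed by Qk knockdown numbered 6 among introns with balanced junctions, 37 with the adjusted p alone, 45 with the rule of 15 points, 12 without siQk 2 and 44 without siQk 1. Alternative 3' splice sites changed by Qk knockdown numbered 17 without siNT 1, 6 without siNT 2, 18 without siQk 2, 16 without siQk 3, 16 with no filter on mean PSI, 24 with sampling variance weights and 34 with the rule of 15 points. Alternative 5' splice sites changed by Qk knockdown numbered 14 without siNT 1, 5 without siNT 2, 32 without siQk 1, 18 with sampling variance weights and 39 with the rule of 15 points. The Eps15 calls were lost without siNT 2 or siNT 3, with limma on PSI and with sampling variance weights, which also ended the call of the Gemin2 site listed at 0 in siNT, and the Isg20 calls without siNT 2 or siQk 3. The call of the Isg20 site that fell was also lost without siNT 1 or siNT 3 and with no filter on mean PSI. For alternative 3' splice sites, grouping siNT 1, siNT 3 and siQk 3 against the other samples also gave 10 calls.

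Junction coverage, a stand-in for gene expression, changed in 493 of 10851 genes: 321 rose and 172 fell. Scaled by the median of log ratios, the split was 251 up and 211 down, so that the share of rises was 54.3% in place of 65.1%. Beside Qk, the largest rises were in Ptgr1, a prostaglandin reductase (log2 fold change 1.86, SE 0.16, adjusted p = 0.00187), Megf10, an engulfment receptor (1.57), the ion channel gene Tmem63a (1.53), Mfge8, which bridges dying cells to phagocytes (1.49), the laminin gene Lamb2 (1.48) and the receptor kinase gene Axl (1.40). The largest falls were in the actin-binding protein gene Avil (log2 fold change -1.76, SE 0.19, adjusted p = 0.00431), the acid-sensing channel gene Asic4 (-1.57), Grap2 (-1.48), Fa2h, an enzyme of myelin lipid synthesis (-1.38), the dynamin gene Dnm3 (-1.34) and Hmcn2 (-1.23). Axl and Fa2h had low coverage, with means of 1.68 and 0.287 CPM in siQk. For Axl the lower group was siNT, with a mean of 0.356 CPM and only 2 reads in siNT 2.

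Interferon response genes lay higher in siQk as a group (15 measured, camera adjusted p = 0.00786), with a median log2 fold change of 0.16. The adjusted p was 0.140 with an estimated correlation. Of the 15, 1 rose, Oasl1 (0.76), and 2 rose when adjusted over the list alone. Glia and mesenchymal genes also lay higher (11 measured, camera adjusted p = 0.0148), with a median of 0.41, and here too the adjusted p was 0.140 with an estimated correlation. In the gene list in junction coverage: glia and mesenchymal genes the camera adjusted p was 0.0625 without siNT 1 and 0.0931 with no filter on gene reads. The matrix protein genes Sparc (1.31) and Fn1 (0.57) and the filament gene Vim (0.50) rose, while the collagen gene Col4a1 fell (-0.60). Adjusted over the list alone, 4 rose and 1 fell.

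Neuronal genes split: of 22 measured, 2 rose and 2 fell (camera adjusted p = 0.493). The hormone granule genes Chga (0.46) and Chgb (0.44) rose, and Ncam1 (-0.34) was among those that fell. Their median was 0.01 and their mean -0.01, and adjusted over the list alone 3 rose and 2 fell. Of 54 splicing regulators 1 changed, also when adjusted over the list alone: Ptbp2, a neuronal repressor of exons, fell (-0.48), and the list's camera adjusted p was 0.110. Of 8 myelin and oligodendrocyte genes Fa2h fell (camera adjusted p = 0.621), and adjusted over the list alone 1 rose and 1 fell. None of the 28 cell cycle genes (camera adjusted p = 0.319) or the 23 cholesterol biosynthesis genes (camera adjusted p = 0.469) passed the test, over all genes or adjusted over the list alone. In the gene list in junction coverage: splicing regulators the camera adjusted p was 0.0233 without siNT 2 and 0.0259 without siNT 3, and in the gene list in junction coverage: cholesterol biosynthesis 0.0279 without siQk 3. The number of genes with changed junction coverage was 176 without siNT 1, 93 without siNT 2, 116 without siNT 3, 934 without siQk 1, 69 without siQk 2, 44 without siQk 3 and 285 with no filter on gene reads. The calls of Tmem63a, Axl, Hmcn2, Oasl1, Fn1, Chga, Chgb, Ncam1 and Ptbp2 were each lost without at least 1 sample, and that of Vim also when scaled by the median of log ratios. The calls of Vim, Fn1, Ncam1 and Tmem63a were also lost with no filter on gene reads, those of Vim and Ncam1 with a mean of 100 reads per gene and that of Ncam1 with a prior of 2 CPM.

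Most microexons that differed in neurons had a lower inclusion with cycloheximide. The authors' deposited table has 2455 microexon entries of 1 to 30 nt, and 229 of them changed: 54 were higher and 175 lower with cycloheximide. Of the 229, the authors' deposited table types 5 as alternative acceptors, and 4 of these overlap a changed cassette exon with its own entry; the 224 cassette exons alone were 53 higher and 171 lower. Among all 2428 cassette entries, changed or not, 1054 were higher and 1374 lower. The counts below use all entries. The median size of the change was 23.4 percentage points. These values carry no SD, since the authors' deposited table gives 1 value per condition, and the direction rests on reading its first column as untreated. The authors' deposited table puts the largest rises in Fblim1, which encodes a filamin-binding adhesion protein (16 nt exon in untranslated sequence, 0.738% to 97.3%), Adh1, an alcohol dehydrogenase (21 nt, 6.63% to 90.2%), the collagen gene Col13a1 (28.8% to 87.7%) and Prom1 (7.12% to 62.7%). They are followed in the authors' deposited table by Syne1, a nuclear envelope protein (43.9% to 89.96%), the centrosome gene Pcnt (49.0% to 93.9%), the myosin gene Myh14 (27.7% to 72.3%) and Chpt1 (40.9% to 83.7%).

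The largest fall in the authors' deposited table was in Srpk2, a kinase of splicing factors, whose 26 nt coding exon (chromosome 5, 23526790 to 23526815) went from 99.7% to 0.337%. The authors' deposited table next lists a 29 nt untranslated exon of the transcription factor gene Zbtb7b (94.3% to 2.70%), a 25 nt exon of Frem1 (91.1% to 5.70%) and 23 nt exons of Phf21b (91.2% to 16.6%), Trim72 (91.2% to 20.5%), Plch1 (90.6% to 21.5%) and Unc13c, a synaptic vesicle priming factor (83.5% to 18.9%). A 24 nt exon of the casein kinase gene Csnk1g1 went from 70.5% to 4.01% in the authors' deposited table.

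Frame-shifting microexons, whose length is not a multiple of 3, behaved differently from frame-keeping ones. The label rests on length alone, and not all entries are coding. Of the 229 changed, 184 lie in coding sequence, 8 in untranslated sequence and 37 in neither. Coding exons were not tested on their own. Of 1061 frame-shifting microexons 64 changed, 6.03%, and of 1394 frame-keeping ones 165 changed, 11.8% (odds ratio 0.478, 95% interval 0.348 to 0.650, Fisher's exact p = 7.88e-07). Among the frame-shifting ones 31 were higher and 33 lower, against 23 higher and 142 lower among the frame-keeping ones (odds ratio for higher 5.74, 95% interval 2.85 to 11.8, Fisher's exact p = 1.60e-07). These tests compare exons within 1 table and do not measure the spread between neuron cultures. For the microexons changed by cycloheximide, a minimum difference of 20 points gave 138, and the Myh14 microexon no longer passed at a probability of 0.95.

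**Figure D4:**
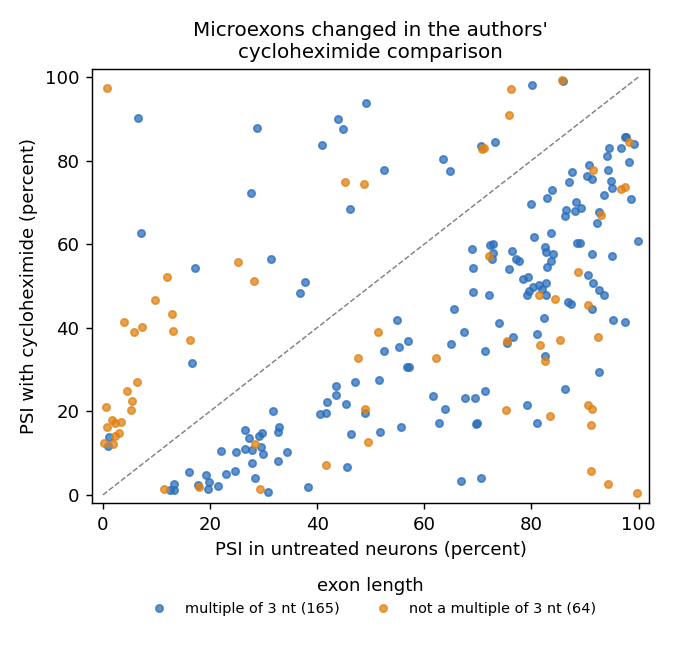
PSI (percent) of the 229 microexons changed in the authors' cycloheximide comparison, untreated on the x axis and cycloheximide on the y axis, with 1 point per entry and the dashed line at equal PSI. Most frame-keeping exons (blue) lie under the line, 142 of 165, and the frame-shifting ones (orange) lie on both sides.

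Of 255 microexons measured in both experiments, 22 changed after Qk knockdown and 72 with cycloheximide, and 8 changed in both where 6.21 would overlap by chance (odds ratio 1.51, 95% interval 0.521 to 4.07, Fisher's exact p = 0.457). Of the 8, 6 rose in siQk and were lower with cycloheximide: those of Dst, Arvcf, Trrap, Pus7, Nckap1 and Tenm3. The 24 nt exon of Ckap5, a microtubule polymerase, was higher in both and the 27 nt exon of Mark3 lower in both. The largest difference among them with cycloheximide was in Trrap, part of histone acetyltransferase complexes: 71.4% to 24.7% in the authors' deposited table, against 23.4% ± 5.85 to 45.2% ± 3.53 (SD, n = 3) after Qk knockdown. The experiments used different cells and were quantified in different formats, so only the overlap was tested.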

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

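Reads thinned to the shallowest library, the narrower gene background, the minimum intron inclusion, the motif over the whole list and cassette exons alone in the neurons were chosen after the data were seen. Over all alternatives, 347 of 401 values of the comparisons stayed on their side of the threshold or, for counts, within 1.5 times. For named events and genes this was so in 903 of 1009 values, 106 were no longer past the threshold and 0 reversed. The drop of Qk, the higher share of microexons, the frame tests in neurons and the excess of changed exons in the cytoskeleton, endocytosis and neuronal microexon lists passed under every alternative run. For microexons changed by Qk knockdown, limma on PSI in percent gave 46, sampling variance weights 47 and the rule of 15 points with a gap of 5 gave 46. For the deposited neural microexon list in the Qk knockdown these gave 33, 34 and 29. Sampling variance weights gave 24 alternative 3' splice sites changed by Qk knockdown and 18 alternative 5' splice sites changed by Qk knockdown, the rule of 15 points gave 34 and 39, and no filter on mean PSI gave 16 alternative 3' sites. Retained introns changed by Qk knockdown numbered 45 under the rule of 15 points, 37 with the adjusted p alone and 6 among introns with balanced junctions. In the gene list in splicing: autism-associated genes, the odds ratio was 6.85 with no filter on mean PSI and 4.54 under the rule of 15 points. Genes with changed junction coverage numbered 285 with no filter on gene reads, where the adjusted p in the gene list in junction coverage: glia and mesenchymal genes was 0.0931. With an estimated correlation it was 0.140 there and 0.140 in the gene list in junction coverage: interferon response. For the deposited upstream motif among list microexons that rose, the classes of the authors' deposited table over the whole list gave an odds ratio of 2.56 (Fisher's exact p = 0.0584) in place of 8.16. For microexons changed by cycloheximide, a difference of 20 points gave 138, fewer by construction. Apart from that one, the cause was not tested.

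With 1 sample left out at a time, the lowest and highest values were 17 to 29 for microexons changed by Qk knockdown, 66 to 120 for longer cassette exons changed by Qk knockdown, 8 to 19 for the deposited neural microexon list in the Qk knockdown (odds ratio against other microexons 1.27 to 2.80), 12 to 44 for retained introns changed by Qk knockdown, 6 to 18 for alternative 3' splice sites changed by Qk knockdown, 5 to 32 for alternative 5' splice sites changed by Qk knockdown and 44 to 934 for genes with changed junction coverage. The odds ratio for the direction of change, microexons against longer cassette exons, ran from 2.52 to 6.29, and in the gene list in splicing: splicing regulators from 1.66 to 4.31. The adjusted p of the gene list in junction coverage: glia and mesenchymal genes ran from 0.00443 to 0.0625, of the gene list in junction coverage: splicing regulators from 0.0233 to 0.590 and of the gene list in junction coverage: cholesterol biosynthesis from 0.0279 to 0.898. Fewer samples lower the power, but the cause was not tested.

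Whether the replicate numbers pair the samples is not settled. Over 12930 exons, the PSI deviations of siNT and siQk samples with the same number correlated at 0.220, -0.0073 and 0.181. Samples 1 and 3 but not 2 matched their own number best. Junction coverage was not checked in this way. With a replicate block, genes with changed junction coverage numbered 1551, 945 up and 606 down, against 493 without it. For microexons changed by Qk knockdown the block gave 30, for longer cassette exons changed by Qk knockdown 131 and for the log2 fold change of Qk junction coverage -2.91, and it moved no other count by over 1.5 times and no list across the threshold. Both Isg20 sites and the Mroh1 microexon were not called with the block. No paired analysis was possible for cycloheximide because the deposited table holds 1 combined value per condition. The planned motif search, with its other motif and window, was not run. The authors' filtered table holds the same exons as the thresholds and changes nothing. Small shifts were mostly missed in exons simulated at this depth and minimum difference, with a fixed spread. There 6% of differences of 10 points were called and 46% of those of 20 points.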

Other observations

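The tests of the separate counting class, of the upstream motif and of a block of nonsense-mediated decay were chosen after their results were seen; the others were set before.

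The response to Qk knockdown differed with exon length. The share of cassette exons called was 5.59% at 3 to 15 nt, 8.43% at 16 to 27 nt, 2.83% at 28 to 60 nt, 0.969% at 61 to 100 nt and 0.453% above 100 nt. Of the 30 called microexons 27 have a length that keeps the reading frame, 90%, against 305 of the 410 tested, 74.4%. Exact matches in GENCODE M21 exist for 142 of the 152 called cassette exons, and 140 lie in coding sequence. Of the 229 microexons changed by cycloheximide 198 have an exact match, 184 lie in coding and 8 in untranslated sequence.

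In 12 of the 137 genes with a called cassette exon, more than 1 exon was called. Clasp1 and Mapt, the gene of the microtubule protein tau, each had 3 exons that rose, while Phldb1 had 2 that rose and 1 that fell. Bin1, Map4k4, Ppfia1 and Trrap each had 2 that rose. In 6 of the 12 genes exons went both ways, among them Dst, Numb, Dnm2, Adgrl2 and Cacnb1. Some of these pairs mirror each other, so their changes may not be separate. The 139 nt exons of Dnm2 went from 28.8% to 56.5% and from 72.2% to 46.0%. Those of Cacnb1 went from 79.6% to 99.2% and from 15.6% to 1.01%. These genes were picked out after their values were seen.

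Microexons changed more often than longer cassette exons after Qk knockdown. The tables argue against a separate counting class for some of the shortest exons as the cause, since the odds ratio was 8.72 (95% interval 5.39 to 13.6, 26 of 329 microexons) outside that class and 5.28 within it (4 of 81). Within 15 strata of mean PSI and reads the common odds ratio was 4.87 (Mantel-Haenszel, 95% interval 3.13 to 7.55), against 8.02 without strata. The excess was thus smaller but remained among exons of like mean PSI and depth. That mean was taken over all 6 samples, and a called change shifts it. The strata therefore cannot decide whether baseline inclusion in siNT explains the excess. The upstream ACTAAY motif went with the rise among tested list microexons (odds ratio 8.16, Fisher's exact p = 0.000642), less so over the classes of the whole list in the authors' deposited table (odds ratio 2.56, Fisher's exact p = 0.0584). No longer exon has a motif value, so whether loss of repression by Qk at upstream sites explains the excess of microexons stays open. Reading frame was not among the strata. Of exons with a frame-keeping length, 27 of 305 microexons and 99 of 5210 longer exons were called. How much of the excess goes with frame was not tested.

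With cycloheximide, changed microexons were mostly frame-keeping and mostly lower. A block of nonsense-mediated decay alone would raise the share of frame-shifting exons among those changed, and their odds ratio was 0.478 (95% interval 0.348 to 0.650). That test took all entries, coding or not, with no PSI minimum and no strata. It cannot tell frame from baseline inclusion or depth, so it does not exclude decay. As to swapped columns, decay in untreated cells would make changed frame-shifting microexons the more extreme in the column read as untreated. Of the 64 changed ones, 44 were so, or 68.8% (exact binomial interval 55.9 to 79.8, p = 0.00369). Frame-keeping ones leaned the same way, 92 of 165 or 55.8%, and the difference between the frames was not tested. The binomial test, against an equal split, therefore cannot exclude a swap. Among frame-keeping microexons with an untreated PSI of at least 10%, those of the deposited neural list fell in 44 of 144 cases, 30.6%, against 98 of 719 others, 13.6% (odds ratio 2.78, 95% interval 1.79 to 4.29, Fisher's exact p = 3.32e-06), and 2.33 within strata (95% interval 1.48 to 3.65). A loss of the neural microexon programme during 12 h without translation may therefore add to the pattern, but the samples were pooled and the depth is unknown, so a difference between cultures stays open.

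Other splits of the 6 N2A samples were counted for each model. There are 10 splits, too few for a share under 0.05. In the real split 30 microexons were called and in the highest other split 0. For longer exons these counts were 122 and 0, for introns 20 and 4, for alternative 5' sites 8 and 2, for junction coverage 493 and 0 and for the neural list 19 and 0, so that in each of these only 1 split, the real one, reached the count. For alternative 3' sites they were 10 and 10, so that 2 splits reached it, the other being siNT 1, siNT 3 and siQk 3 against the rest.

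A further set of hypotheses was tested on the same data. The response may fall off with length beyond the microexon limit: exons of 28 to 60 nt were called in 53 of 1876 cases and longer ones in 69 of 10643 (odds ratio 4.45, 95% interval 3.04 to 6.49, Fisher's exact p = 3.32e-14). The ratio was 3.52 within strata of mean PSI over all 6 samples, with read depth not stratified. Changed longer exons may keep the reading frame more often: 99 of 5210 frame-keeping and 23 of 7309 frame-shifting exons were called (odds ratio 6.14, 95% interval 3.86 to 10.1, Fisher's exact p = 4.38e-19). Here too the strata were of mean PSI over all 6 samples alone, and the ratio within them was 4.54. Frame was read from length, whether or not an exon is coding. Genes with a changed exon may also change in junction coverage more often: 16 of 137 did, against 222 of 5528 others (odds ratio 3.16, 95% interval 1.72 to 5.46, Fisher's exact p = 0.000178). Within strata of mean siNT coverage the ratio was 3.08, though reads of a changed exon enter the coverage of its own gene.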
